A study of Mus musculus with 8 samples.

How the data were processed

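Whole kidneys of 8 mice were profiled by RNA-seq, 4 labelled knockout and 4 labelled wildtype. Per the labels' protocols, RNA was extracted with Trizol, 200 ng of total RNA entered a directional library kit, and 15 PCR cycles were run. The deposited values are counts of reads per gene, one file per library, whole numbers with no normalization, as the values themselves show. Per the submitters' processing notes, STAR, HTSeq and edgeR were used with the mouse build mm9; versions, annotation and the role of each tool are not given in the sources used here. The deposited counts are named as not stranded although the kit marks strand, so that reads of a gene and of an overlapping antisense partner cannot be told apart.

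Each file held 37583 gene rows and the counter's summary rows, which stayed out of library sizes and tests. Of all records, 63.8% to 69.1% were assigned to a gene, 13.0% to 16.8% to no feature, 2.17% to 2.42% to more than 1 gene, and 15.3% to 18.0% were not unique alignments. Symbols were taken from a gene name table, which matched 32860 of the identifiers. Of 449 entries in the gene lists, 432 had a row and 401 were tested. The 17 without a row included the 13 mitochondrially encoded genes. Gene counts per library came to 13435113 to 17930347. Intervals and floors given for counts cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

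Genes were kept by edgeR's filterByExpr, which left 15228, and were scaled by TMM factors. The groups were compared with edgeR's quasi-likelihood test (R 4.3.3, edgeR 4.0.16, robust fit, no covariate), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. CPM values are TMM-normalised, except the summed CPM of genes that were not tested, which use the library totals. Gene lists with at least 5 tested genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with adjustment over the 29 lists tested, and again with an estimated correlation and with fry. Single values were compared by exact two-sided permutation over all 70 assignments, for which the smallest possible p is 0.0286. The model was also refitted to all 35 splits of the libraries into 4 and 4.

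The gene lists of the report, the tests between the groups and the other settings, except those named below as added, were fixed before the data were examined. The lists of BMP and p53 targets and most tests of explanations were chosen later, as stated where they appear. Named genes are all tested AP-2 and KCTD list members; the 10 rising and 10 falling genes with the largest absolute log2 fold change among those with adjusted p under 0.05, mean log2 CPM of at least 1, a symbol that is not a predicted model, and no overlap between the groups; and, for each list, up to 4 members with the smallest adjusted p. Other members of the fixed lists and genes chosen after their values were seen are named as such where they appear.

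The fit was tested on simulated data drawn from the means and library sizes of the 15228 genes. With edgeR, 56% of 50 genes changed 1.5-fold, 80% of 50 changed 2-fold and 98% each of 50 changed 4-fold and 50 changed 8-fold were recovered. There were 11 false calls, 5.88% of all calls. The share of false calls was 14.3% with DESeq2 and 6.99% with limma voom. Camera and fry each called the 1 list planted with a log2 change of 0.8 and none of 30 unchanged lists. The simulated genes were drawn independently of each other, whereas real lists are correlated, with an estimated correlation of 0.813 for the red cell list. The simulation therefore could not show false list calls that come from correlated genes.

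The other settings were DESeq2's size factors, library totals only, upper quartile factors, DESeq2 1.42.0, limma voom, no filter, a stricter filter of at least 1 CPM in at least 4 libraries, thresholds of 0.01 and 0.10, a replicate block, 1 surrogate variable (sva 3.50.0), library totals without the 20 highest genes, and leaving out each library in turn. A clock gene score as a term, a fit without knockout libraries 1 and 4, and the segment lists without Pvalb and Abca13 were added after seeing the data. Libraries of the same group were clearly distinct, with a chi-square per degree of freedom of 9.49 to 25.3 between pairs. Nothing in the labels ties the replicates to litters or days.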

Results

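The series compared whole kidneys of mice with an inducible deletion of Tfap2b, driven by a tamoxifen-responsive Cre recombinase under a beta-actin promoter, with kidneys of control littermates. Tfap2b encodes AP-2 beta, a transcription factor of the distal nephron. The question was which kidney transcripts differ between the genotypes. Each group held 4 libraries, with 13435113 to 17930347 gene counts per library in those labelled knockout and 13783857 to 17741722 in those labelled wildtype. All 8 libraries held at most 3 counts over the Y-linked genes and at least 10122 counts of Xist.

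Whole-gene counts of the targeted gene were higher, not lower, in the libraries labelled knockout. Tfap2b (ENSMUSG00000025927) stood at 238.1, 266.5, 237.0 and 240.3 CPM in the libraries labelled knockout and at 94.3, 104.9, 110.5 and 102.8 CPM in those labelled wildtype. Its counts were 2.38-fold higher in the libraries labelled knockout (log2 fold change 1.25 ± 0.074 (SE), edgeR adjusted p = 4.18e-06; exact permutation p = 0.0286, the smallest the design allows). Counts over the whole gene include exons outside any deleted part, so they do not check the deletion. All directions below are therefore those of the libraries labelled knockout against those labelled wildtype. Of the related genes, Tfap2a, a second AP-2 factor, rose (log2 fold change 0.85 ± 0.14 (SE), edgeR adjusted p = 0.00318), and Kctd1, a repressor that binds AP-2 factors, fell (-0.34 ± 0.077, adjusted p = 0.0157; adjusted p = 0.0737 with library totals only). Kctd15 had a log2 fold change of 0.07 ± 0.18 (adjusted p = 0.85). With the clock score as a term, a fit chosen after seeing the data, 1 of these 4 genes rose, Tfap2b, and 0 fell. The median of the 4 was then 0.36 against 0.46. With a replicate block, or without knockout libraries 1 and 4, 2 rose and 0 fell.

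**Figure D1:**
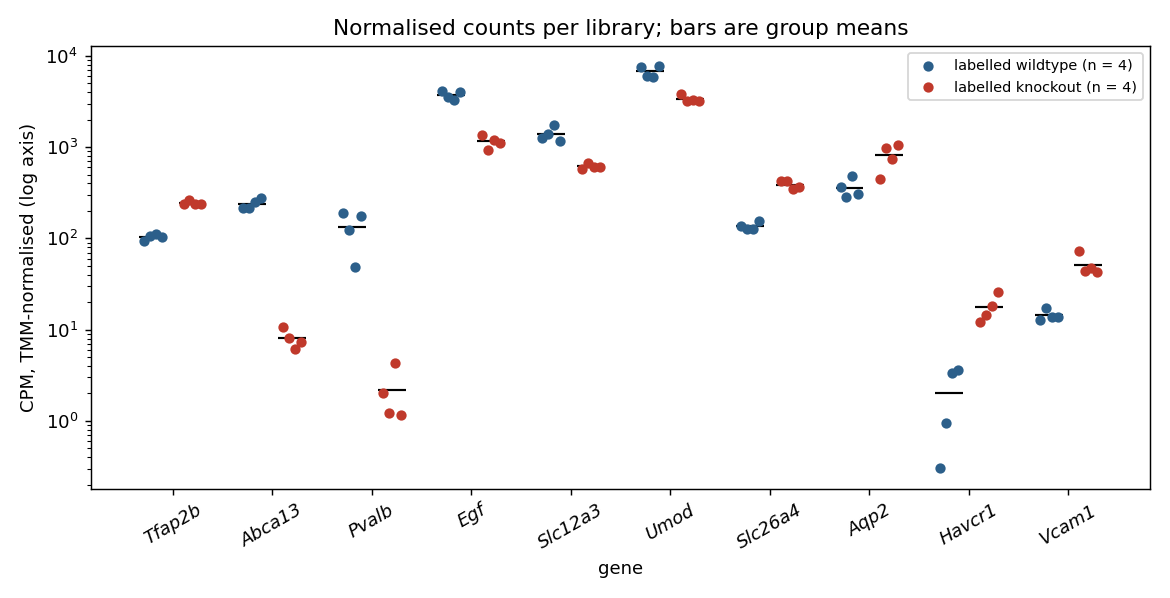
TMM-normalised CPM on a log axis for 10 genes, with 1 point per library (n = 4 per group) and bars at the group means. Tfap2b lies at 237.0 CPM or above in each library labelled knockout and at 110.5 CPM or below in each labelled wildtype, while Abca13 and Pvalb separate in the opposite direction.

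Markers of the distal convoluted tubule fell. Of 13 measured list members, 11 fell, none rose and 2 did not pass the test; adjusted over the list alone, 12 fell. Parvalbumin, Pvalb, went from 134 ± 63.4 to 2.18 ± 1.47 CPM (SD, n = 4 each), and Abca13 from 240 ± 30.2 to 8.06 ± 1.87 CPM. Slc12a3, the thiazide-sensitive sodium chloride cotransporter, fell by 1.16 ± 0.12 (SE) on the log2 scale, Egf, the epidermal growth factor precursor, by 1.70 ± 0.13, and Trpm6, a magnesium channel, by 0.80 ± 0.11. Sall3 and Kcnj16 had log2 fold changes of -0.18 and -0.23. The list's median log2 fold change was -0.61 (camera adjusted p = 1.51e-12, and adjusted p = 0.0278 with an estimated correlation). In the fit with the clock score as a term, 8 of the 13 fell, with a list median of -0.59.

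Of 17 thick ascending limb and macula densa markers, 9 fell, none rose and 8 did not pass the test; adjusted over the list alone, 9 fell and 1 rose. Umod, which encodes uromodulin, fell by 1.01 ± 0.12 (SE) on the log2 scale, Bsnd, a chloride channel subunit, by 1.07 ± 0.087, Ptger3 by 0.91 ± 0.11 and Cldn16, a tight junction protein, by 0.78 ± 0.11. The camera adjusted p was 0.000215, and adjusted p = 0.258 with an estimated correlation. Set against each other in each library, the distal convoluted tubule list lay 0.68 ± 0.10 log2 units (SD, n = 4) above the thick ascending limb list in the libraries labelled wildtype and -0.32 ± 0.11 in those labelled knockout, a difference of -1.004 (exact permutation p = 0.0286). That difference rests on Pvalb and Abca13: without these 2, left out after seeing the data, it was -0.28 (exact permutation p = 0.0571). The median log2 fold changes of the lists were -0.61 and -0.48.

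Principal and intercalated cell markers that passed the test rose, while connecting tubule and calcium transport genes moved both ways. Of 11 principal cell markers, 8 rose, none fell and 3 did not pass; adjusted over the list alone, 8 rose and 1 fell. Aqp3, a basolateral water channel, rose by a log2 fold change of 1.18 ± 0.20 (SE), the sodium channel subunits Scnn1b and Scnn1g by 0.66 ± 0.096 and 0.56 ± 0.077, and the transcription factor Gata3 by 0.57 ± 0.11. Camera gave the list adjusted p = 0.00205, and adjusted p = 0.274 with an estimated correlation. Without knockout 2, knockout 3 or wildtype 4, 5 principal cell markers rose in each case. A replicate block left 4 rising. With a circadian clock score of each library as a term, a fit chosen after seeing the data, 2 rose, with a list median of 0.42 against 0.56. Of 14 intercalated cell markers, 8 rose, none fell and 6 did not pass; adjusted over the list alone, 9 rose and 1 fell. Slc26a4, the chloride-bicarbonate exchanger pendrin, rose from 137 ± 12.7 to 389 ± 41.3 CPM (SD, n = 4 each), and Hmx2, Insrr and Slc4a9 by log2 fold changes of 1.77 ± 0.14, 1.04 ± 0.077 and 0.86 ± 0.076 (SE). The camera adjusted p was 3.49e-06, and adjusted p = 0.258 with an estimated correlation. Of 8 connecting tubule and calcium transport genes, S100g rose (1.61 ± 0.24), Calb1 fell (-1.21 ± 0.092) and Atp2b4 fell (-0.54 ± 0.094), and 5 did not pass; the list's median was -0.07 (0.04 with library totals only), its mean 0.05, and camera gave it a downward direction (adjusted p = 0.603), as did fry (adjusted p = 0.0389). Without knockout 1, 2 of these genes rose.

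Among 20 tubule transcription factors, 7 rose, 4 fell and 9 did not pass; adjusted over the list alone, 7 rose and 5 fell. Prox1 fell by 1.32 ± 0.12 (SE) on the log2 scale, Lhx1 by 0.97 ± 0.13 and Emx1 by 0.51 ± 0.090, while Foxi1, required for intercalated cells, rose by 1.03 ± 0.15. The camera adjusted p was 0.699; without knockout 2 or wildtype 4, 4 of these factors rose, and with the clock score as a term none rose and 2 fell, with a median of 0.03 against 0.04. Of 20 proximal tubule markers, 5 fell, none rose and 15 did not pass; adjusted over the list alone, 8 fell. Slc5a2, a sodium glucose cotransporter, fell by 1.30 ± 0.23, Ass1 by 0.99 ± 0.16 and the endocytic receptor gene Lrp2 by 0.68 ± 0.17. Lrp2 did not pass without knockout 4, wildtype 3 or wildtype 4 (adjusted p = 0.063, 0.0587 and 0.0617). For the list, camera gave adjusted p = 6.34e-05, and adjusted p = 0.283 with an estimated correlation. The proximal count was 9 with DESeq2, 3 with library totals only, 3 without knockout 2, wildtype 1, wildtype 2 or wildtype 4, 2 without knockout 4 or wildtype 3, and 0 with the clock score as a term, where the list's median was -0.38 against -0.35. Slc34a3 and Pth1r, 2 of 3 falling members among 9 vitamin D and phosphate genes (also 3 adjusted over the list alone), fell by 1.51 ± 0.21 and 0.73 ± 0.10 (camera adjusted p = 0.00657; adjusted p = 0.283 with an estimated correlation). With the clock score as a term, 1 of the 9 fell, with a list median of 0.01 against -0.17.

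**Figure D2:**
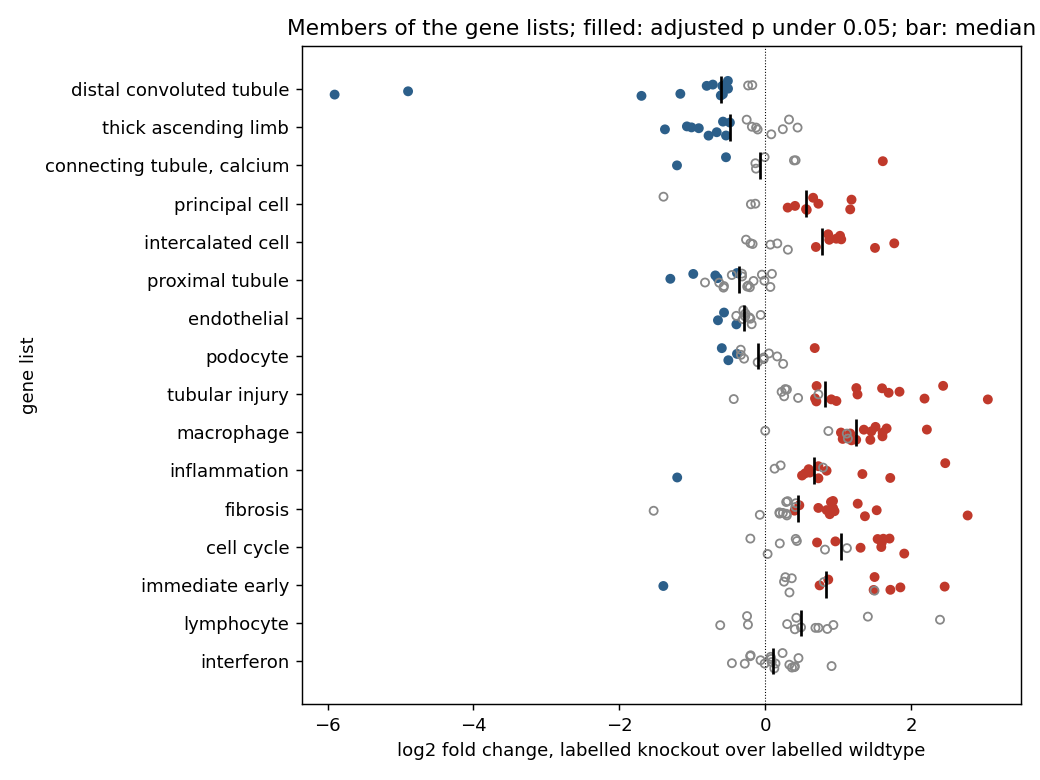
Log2 fold changes of the members of 16 gene lists, with filled points for genes with edgeR adjusted p under 0.05, open points for the others and a bar at each list's median. Distal convoluted tubule members lie at or below -0.18, and 13 of 20 tubular injury genes rose.

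Tubular injury genes rose. Of 20 measured, 13 rose, none fell and 7 did not pass; adjusted over the list alone, 15 rose and 1 fell. Havcr1, which encodes the injury marker KIM-1, went from 2.04 ± 1.65 to 17.7 ± 5.92 CPM (SD, n = 4 each), Vcam1 from 14.4 ± 2.09 to 51.6 ± 13.9 CPM, and Cdkn1a, a cell cycle inhibitor, from 10.9 ± 2.48 to 49.2 ± 16.0 CPM. Lcn2, which encodes NGAL, rose by a log2 fold change of 1.27 ± 0.17 (SE). The camera adjusted p was 1.34e-09, and adjusted p = 0.0278 with an estimated correlation. With the clock score as a term, 4 injury genes rose, with a list median of 0.78 against 0.82.

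Of 17 macrophage and dendritic cell markers, 13 rose, none fell and 4 did not pass; adjusted over the list alone, 15 rose. Mrc1 rose by a log2 fold change of 1.51 ± 0.11 (SE) and the complement genes C1qc, C1qb and C1qa by 1.35 ± 0.16, 1.25 ± 0.17 and 1.17 ± 0.17; Csf1r, which did not pass, had 0.00 ± 0.084. With camera the macrophage list had adjusted p = 4.95e-11, and adjusted p = 0.258 with an estimated correlation. The clock score as a term gave 13 macrophage genes rising, with a list median of 1.665 against 1.248. Of 14 inflammation genes, 10 rose, 1 fell and 3 did not pass; adjusted over the list alone, 11 rose and 1 fell. Ccl2, a monocyte chemoattractant, rose by 2.47 ± 0.30 and Tnfaip2 fell by 1.21 ± 0.11 (camera adjusted p = 6.19e-06; adjusted p = 0.258 with an estimated correlation). Of 24 matrix and fibrosis genes, 13 rose, none fell and 11 did not pass; adjusted over the list alone, 16 rose and 1 fell. Timp1 rose by 2.78 ± 0.49, Mmp2 by 1.27 ± 0.19 and Dcn by 0.93 ± 0.12 (camera adjusted p = 7.25e-08; adjusted p = 0.258 with an estimated correlation). With the clock score as a term, 6 fibrosis genes rose, with a list median of 0.69 against 0.44. Without knockout libraries 1 and 4, a fit chosen after seeing the data, 8 macrophage, 8 injury, 5 inflammation, 4 fibrosis, 5 principal cell and 4 cell cycle genes rose. In that fit 1 injury gene and 2 proximal tubule genes fell. The list medians were 1.025 against 1.248 in the main fit for macrophage, 0.86 against 0.82 for injury and 0.58 against 0.67 for inflammation genes. For fibrosis genes they were 0.41 against 0.44 and for principal cell markers 0.55 against 0.56. Cell cycle genes had 0.85 against 1.04 and proximal tubule markers -0.34 against -0.35.

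Of 16 cell cycle genes, 9 rose and 7 did not pass; adjusted over the list alone, 13 rose. Cdk1 rose by 1.59 ± 0.28 and Top2a by 1.54 ± 0.33, with adjusted p = 0.0549 for Top2a without wildtype 3. The camera adjusted p was 1.87e-06, and adjusted p = 0.258 with an estimated correlation. Without wildtype 1, 5 cell cycle genes rose, and with a replicate block 3 rose. The clock score as a term gave 11 rising, with a list median of 1.74 against 1.04. Of 14 immediate early genes, which also respond to tissue handling, 7 rose, 1 fell and 6 did not pass; adjusted over the list alone, 11 rose and 1 fell. Egr1 rose by 1.49 ± 0.18 and Atf3 by 1.85 ± 0.26 (camera adjusted p = 1.2e-06; adjusted p = 0.258 with an estimated correlation). With the clock score as a term, 3 rose, with a list median of 0.74 against 0.83. Of 13 lymphocyte markers and 18 interferon-stimulated genes, edgeR called none; their medians were 0.49 and 0.11, and camera gave adjusted p = 0.0435 and 0.603, with adjusted p = 0.579 and 0.853 with an estimated correlation. At an unadjusted p under 0.05, edgeR had 2 genes in each list; DESeq2 called 2 lymphocyte and 0 interferon genes, and limma voom 0 in both.

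Over all genes, 1817 of 15228 differed (edgeR adjusted p under 0.05), of which 949 rose and 868 fell; 498 differed at least 2-fold, 351 upward and 147 downward. At an unadjusted p under 0.05 there were 4133. Of 29 gene lists, camera called 19, 11 upward and 8 downward. Of these, 2, distal convoluted tubule and tubular injury, were called with an estimated correlation. Other splits of the libraries gave up to 20 lists, in a split with 3 of the libraries labelled knockout on 1 side. Fry, which does not compare a list with other genes, called 19, not the lymphocyte and male-biased lists (adjusted p = 0.309 and 0.0608) but the connecting tubule and clock lists (adjusted p = 0.0389 and 0.0441). The groups did not overlap for 2812 genes, 18.5% of those tested, where chance gives 2.86%. The TMM factors differed between the groups, at 1.04 ± 0.029 and 0.96 ± 0.0096 (SD, n = 4 each; exact permutation p = 0.0286). With library totals only, the median log2 fold change of all genes moved from 0.00 to 0.11, with 1658 genes rising and 508 falling, 76.5% upward against 52.2%. Without knockout libraries 1 and 4, 912 genes differed.

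**Figure D3:**
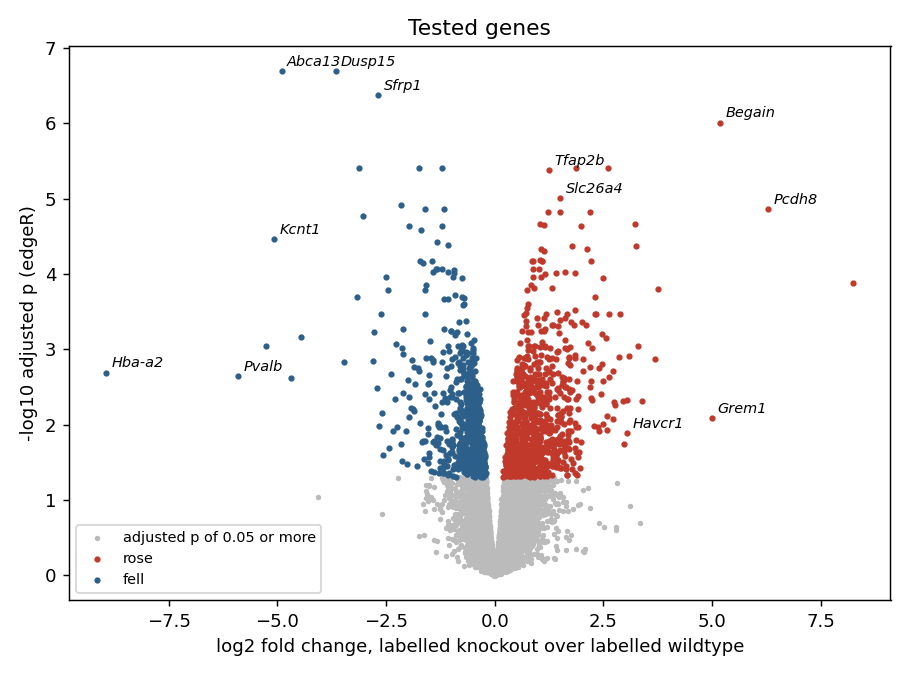
Log2 fold change (labelled knockout over labelled wildtype) against -log10 of the edgeR adjusted p for 15228 genes, with the 949 rising and 868 falling genes coloured. Abca13 and Begain lie among the genes with the smallest adjusted p.

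The rising genes with the largest fold changes under the naming rule were Pcdh8, a protocadherin, at 9.69 ± 4.16 CPM against 0.12 ± 0.043 (SD, n = 4 each), Begain at 9.24 ± 0.94 against 0.24 ± 0.11, and Grem1, a secreted BMP antagonist, at 29.6 ± 16.7 against 0.92 ± 0.43. Gpr176, Fcrls, Adgra1, Havcr1, Aqp8, Col6a4 and Timp1 followed, with log2 fold changes of 3.25 to 2.78; Aqp8 did not pass without wildtype 2 or wildtype 3 (adjusted p = 0.0527 and 0.0618). Pcdh8 had 7 counts over the 4 libraries labelled wildtype and 617 over those labelled knockout. The falling genes were Hba-a2, Pvalb, Kcnt1, Abca13, Slc6a7, Dusp15, Shd, Lrtm2, Sfrp1 and Nacad. Kcnt1, a sodium-activated potassium channel gene, went from 42.3 ± 7.84 to 1.24 ± 0.81 CPM, Dusp15 from 29.8 ± 3.31 to 2.35 ± 0.37, and Sfrp1, a secreted Wnt modulator, from 314 ± 33.6 to 49.1 ± 6.78. Hba-a2, an alpha globin gene, is uncertain because it may share reads with the near-identical Hba-a1. Such sharing was not tested. Hba-a1 had a log2 fold change of -0.29 ± 0.27 (adjusted p = 0.553).

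Measures other than genotype also moved with single libraries or with the groups. The circadian clock score, the mean log2 CPM of output genes minus that of activator genes, was -0.17 ± 1.36 in the libraries labelled knockout and 2.62 ± 1.33 in those labelled wildtype (SD, n = 4 each; exact permutation p = 0.0571). Knockout 1 scored 1.78, between wildtype 1 at 0.97 and wildtype 2 at 2.46. The score was entered as a term in a fit chosen after seeing the data, which called 748 genes. The 1261 genes whose call ended there kept a median 0.872 of their log2 fold change (quartiles 0.69 and 1.06), while their standard errors grew by a median factor of 1.54. In 9 adrenal genes too low to be tested, knockout 4 held 184.6 CPM, against 0.142 to 2.24 CPM in the other libraries. Of 5 red cell transcripts, 1, Hba-a2, fell, 3 fell without knockout 3, 4 with DESeq2 and 4 adjusted over the list alone (median -1.16, camera adjusted p = 0.000899, and adjusted p = 0.283 with an estimated correlation). Without knockout libraries 1 and 4, 0 of 6 tested fell, with a median of -0.78.

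**Figure D4:**
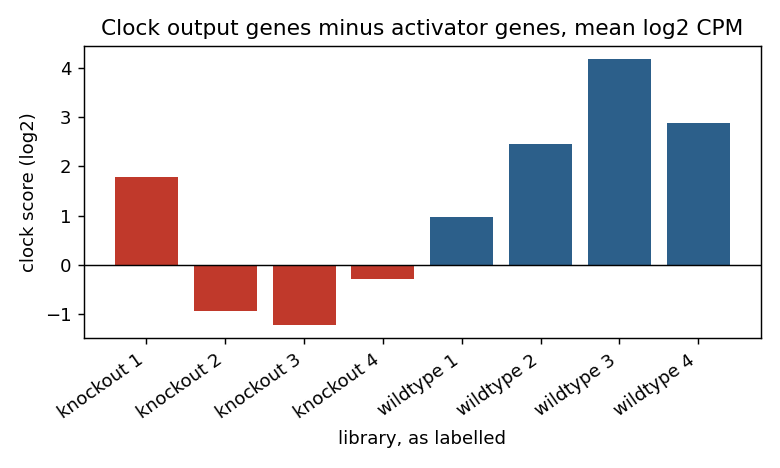
Clock score (log2) of each library as labelled, with bars from 0. Knockout 1, at 1.78, lies above wildtype 1, at 0.97, and the other libraries labelled knockout lie below 0.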

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

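The tests of Tfap2b, of the distal convoluted tubule markers and of the clock were chosen after their values were seen; the splits of the libraries were set before their results were read.

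In 346 groups of 4 values (named genes, list means and library measures), 15 had a library far from the other 3, as measured by its gap over the range; chance gives about 1 in 20. Knockout 1 was apart for Grem1 (lowest, 0.8372), Kcnt1 (highest, 0.8996), Ccnb2 (highest, 0.9239), Top2a (highest, 0.8381), Atf3 (lowest, 0.8295), Vcam1 (highest, 0.8372) and Emx1 (lowest, 0.9113). Knockout 2 was highest for Tfap2b (0.8827), knockout 3 lowest for the urothelium list (0.8746), and knockout 4 lowest for Col6a4 (0.8719) and highest for Star (0.9081). Wildtype 1 was lowest for Gpr176 (0.9441) and highest for Hbb-bs (0.9345), and wildtype 3 lowest for Cyp51 (0.9924) and Ifit2 (0.8527). In 9 adrenal genes too low to be tested, knockout 4 held 184.6 CPM, against 0.142 to 2.24 CPM elsewhere; Hsd3b1 had 962 counts, Cyp21a1 812 and Cyp11b1 429 there, while Th and Dbh had 0.

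Tfap2b counts were higher in all 4 libraries labelled knockout than in any labelled wildtype, which argues against a single mislabelled library (4 of 4 above). Scaling is argued against by the lowest log2 fold change over the scaling alternatives, 1.25. An exchange of all labels cannot be told apart from a transcript of the remaining exons made at a higher level, because both give a group-wide difference. Esr1, which resembles part of the Cre fusion, was higher in the libraries labelled knockout (log2 fold change 1.668, edgeR adjusted p = 0.000984), but the endogenous gene could give the same counts. The genotype, as labelled, stays an open and untested explanation.

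Distal convoluted tubule markers fell unequally. An even loss of cells across the segment, with unchanged expression in the rest, would lower no marker made only there further than Slc12a3. Yet 3 of the other 12 members fell further by over 2 SE (Pvalb, Abca13 and Egf). Their log2 fold changes differed from that of Slc12a3 by -4.74, -3.73 and -0.53, and the remaining members fell less than Slc12a3. Whole-kidney counts do not show whether a marker such as Egf is made only in this segment. A loss of one part of the segment stays open. Dilution by immune and stromal cells would lower all tubule lists alike, and the principal cell list instead rose by 1.77 log2 units against the distal convoluted tubule list (exact permutation p = 0.0286; 1.05 without Pvalb and Abca13, p = 0.0286). Changed expression in the remaining cells with the labelled genotype may be part of the pattern, as a hypothesis. These values do not separate it from an uneven loss of cells.

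The clock score was lower in 3 libraries labelled knockout than in any labelled wildtype. With the score as a term, 748 genes were called, against at most 19 in the other 34 splits fitted in the same way. Each of those splits mixes libraries of both labels, which by itself lowers its calls. The comparison therefore cannot decide on phase, which a linear score may also follow poorly. Of the 1817 genes called without the term, 556 (30.6%) were also called with it. The other 1261 kept a median 0.872 of their fold change while standard errors grew 1.54-fold, so at the median wider errors weighed more than smaller folds; called genes vary little within a group, which by itself favours a ratio near 1. Phase stays open for all of the called genes. Of the 1261, 121 had a fold change under 0.5 of its size without the term, among them Cry1 (log2 fold change 1.2 ± 0.32 to 0.40 ± 0.43, SE).

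Of the 35 splits of the libraries, only the real one gave as many genes differing (1817 against at most 23 in the others). The same held for genes rising (949 against at most 17), falling (868 against at most 17) and differing at least 2-fold (498 against at most 18). Every other split puts libraries of both labels in each group, which widens the spread there and by itself lowers the calls. A share of 1 in 35 is also the smallest possible, so the comparison cannot exclude chance. Nor is chance excluded for the number of gene lists called with the preset correlation. There, 4 of the 35 splits gave 19 or more, the highest other being 20. Besides the real one, these held 3 libraries labelled knockout and 1 labelled wildtype in 1 group. They thus keep part of the real contrast. Splits with 2 libraries of each label per group gave 1 to 11 lists. The number of lists therefore cannot decide on chance.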

How the results depend on the processing

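The clock term, the fit without knockout libraries 1 and 4 and the lists without Pvalb and Abca13 were chosen after seeing the data. No named gene or list changed sign with a call in any alternative run. Genes differing came to 706 at a threshold of 0.01, 2850 at 0.10, 748 with the clock term and 912 without knockout libraries 1 and 4, against 1817. Genes rising came to 1658 with library totals only, 380, 1440, 517 and 502 in the same order, against 949. Genes falling came to 508 with library totals only, 326, 1410, 231 and 410, against 868. Genes differing at least 2-fold came to 285 at 0.01. The cause of the change with library totals only was not tested beyond the shift of the median gene, and with the clock term the 1261 lost genes kept a median 0.872 of their fold change with standard errors 1.54 times as large. Leaving out 1 library at a time gave 1076 to 1940 genes differing, 588 to 977 rising, 488 to 963 falling and 390 to 539 at least 2-fold, with the lowest counts without knockout 2 (1076) and knockout 4 (1176); falling genes were 517 without knockout 4 and 576 without wildtype 3. Fewer libraries alone lower such counts. Tfap2b ranged from 1.209 to 1.285 and the difference of the segment lists from -1.052 to -0.9691; without Pvalb and Abca13 the latter was -0.2804 (exact permutation p = 0.0571), since they fell furthest.

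No pairing by replicate number was seen, though so few correlations cannot exclude it. The correlations of same-numbered libraries were -0.22, -0.21, -0.053 and 0.16, and 1 of 4 libraries correlated best with its own number. With a replicate block, 1094 genes differed, 577 rising and 517 falling; the segment difference of -1.004 had p = 0.125 by exact sign flips, the smallest 4 pairs allow. With an estimated correlation 2 lists were called, against 19; leaving out 1 library gave 17 to 19. Of 3079 comparisons of named genes with their main value, 2769 kept their call, 245 lost it and 65 gained it. Library totals without the 20 highest genes changed no call and say nothing, since TMM rescaled all libraries alike. A sex term could not be run because all libraries look female, nor library totals without mitochondrially encoded genes, of which 0 have a row. In simulated data of this depth and group size, 56% of 1.5-fold changes were recovered; neither was varied, so which limits weak changes was not tested.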

Other observations

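The tests of BMP and p53 target genes were set before the values of the members tested were seen; the intercalated cell test and the genes named here were chosen after their values were seen.

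The intercalated cell markers moved unequally. Slc26a4, Insrr, Hmx2 and Slc4a9, markers of cells other than type A, rose. The type A markers Slc4a1, Aqp6 and Kit had log2 fold changes of -0.20, -0.17 and 0.17 and did not pass the edgeR test. Foxi1, Atp6v1g3, Atp6v0d2 and Atp6v1c2, which were assigned to neither type here, had log2 fold changes of 1.03, 0.97, 0.88 and 0.70. A larger share of all intercalated cells would raise all list members alike only if no other cells expressed them. Of the 14, 6 lay over 2 SE below the list's median of 0.78 (Slc4a1, Aqp6, Kit, Atp6v1b1, Atp6v0a4 and Rhcg). Slc4a1 is also expressed in red cells, and whole-kidney counts do not show which cells express the others. The test therefore cannot decide on a larger share. A shift between subtypes and a change of expression within cells also stay open, as hypotheses that were not tested.

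Of genes picked for their values, Grem1, a secreted BMP antagonist, rose by a log2 fold change of 5.005 and Bmp3 by 2.18, while Sostdc1, another secreted antagonist, fell by 1.17. Id1, a BMP target, fell by 1.52 and Smad9, an intracellular mediator, by 1.76. The antagonists thus went both ways, and lower BMP signalling is a hypothesis. Of 8 further target genes, 3 fell (Id2, Id4 and Smad6) and none rose, with a median of -0.467, but camera gave p = 0.172 with an estimated correlation, so the test could not decide.

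Cdkn1a and Gdf15, which p53 can activate, rose by 2.19 and 2.44. Of 14 other p53 targets, 5 rose (Ccng1, Phlda3, Trp53inp1, Aen and Ephx1) and none fell. The rest did not pass, among them Mdm2 (0.20, edgeR adjusted p = 0.135) and Sesn1 (-0.02, edgeR adjusted p = 0.899). The median of the 14 was 0.342 (camera p = 0.0157 with an estimated correlation). This is consistent with p53 activation in the libraries labelled knockout, as a hypothesis; injury and proliferation raise some of these genes by other routes.

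Arhgap36 had 0 counts in all 4 libraries labelled wildtype and 30 to 51 in those labelled knockout, at least 12.0-fold higher at a floor of 3 counts per library. Hba-a2 had 4 counts over the libraries labelled knockout and 1909 over those labelled wildtype, a ratio of 518.9 (95% interval 202.3 to 1906). That ratio is uncertain, since reads may be shared with Hba-a1. Of 30 tested genes that neighbour Tfap2b by order, 2 differed (Tmem70 and Gsta3; 6.67%, Fisher's exact p = 0.572). Of 3 genes higher in female mouse kidney, Prlr and Slc7a12 fell by 1.06 and 0.61 and Cyp4a14 rose by 0.66; of 7 higher in male kidney, Cyp2j13 rose by 1.497 and 6 did not pass. Ren1 fell by 1.06 ± 0.28 (SE). The calls of Prlr, Slc7a12 and Ren1 were each lost in 5 of the 8 fits that left out 1 library, and that of Cyp4a14 in 7.

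Of nuclear-encoded respiratory chain subunits, 6 of 15 fell, of endothelial markers 3 of 12 and of genes mutated in cystic disease 3 of 17, with camera adjusted p of 3.64e-06, 0.000158 and 0.00133, and adjusted p = 0.258, 0.283 and 0.283 with an estimated correlation. The first 2 counts moved with single libraries. Respiratory chain genes that fell numbered 1 without knockout 2 or wildtype 2, 2 without knockout 4, wildtype 1, wildtype 3 or wildtype 4, 3 without knockout 1, 1 with library totals only and 10 with DESeq2. Endothelial genes that fell numbered 1 without knockout 2, knockout 4, wildtype 1, wildtype 2 or wildtype 4, 6 without wildtype 3, 1 with library totals only and 5 with DESeq2. Without knockout libraries 1 and 4, both counts were 0 in edgeR. Urothelium (2 of 7 rose), male-biased (1 of 7 rose, 2 without wildtype 4) and lymphocyte lists (0 of 13) had camera adjusted p of 0.0233, 0.0494 and 0.0435, and adjusted p = 0.283, 0.283 and 0.579 with an estimated correlation; their calls were lost in 1, 4 and 4 of the 8 fits that left out 1 library. Camera called none of the lists of podocyte (1 rose, 3 fell of 13), mural and renin (1 fell of 9), cholesterol (2 fell of 17), fatty acid (2 rose, 1 fell of 18), heat shock (0 of 14), clock (1 rose, 1 fell of 14), adipose (0 of 10) and interferon genes (0 of 18); fry called the clock list downward (adjusted p = 0.0441). With DESeq2, 3 clock genes rose and 4 fell and 5 fatty acid genes rose and 2 fell; with limma voom, no clock gene rose and 5 fell and 4 fatty acid genes rose. For heat shock and adipose genes, edgeR had 4 and 0 at an unadjusted p under 0.05, and DESeq2 called 2 and 0 and limma voom 0 and 0. Single libraries moved these counts too. Without knockout 1, 3 heat shock and 4 fatty acid genes rose, and 2 clock genes rose and 5 fell. Without wildtype 1, 3 clock genes fell and none rose, and without knockout 2, knockout 4, wildtype 2, wildtype 3 or wildtype 4 no clock gene was called, and without knockout 3 none fell. Without wildtype 2, 1 heat shock gene fell. Podocyte genes that fell numbered 1 without knockout 2, knockout 4 or wildtype 2. Cholesterol genes that fell numbered 0 without knockout 2, knockout 4, wildtype 2 or wildtype 4 and 1 without knockout 3, wildtype 1 or wildtype 3. Fatty acid genes that rose numbered 0 without knockout 2, wildtype 1, wildtype 2 or wildtype 4 and 1 without knockout 3 or knockout 4, and none fell without knockout 2, knockout 3, knockout 4, wildtype 1 or wildtype 3. The falling mural gene was not called without knockout 2, knockout 4, wildtype 1, wildtype 3 or wildtype 4, and 1 mural gene rose without knockout 3.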
